A study of Mus musculus with 75 samples.

How the data were processed

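Single-cell RNA was measured by MARS-seq, a 3′ end method, in cells sorted into plates of wells from Foxa2-Venus mouse embryos and from cultured embryonic stem cells led to endoderm. The authors deposited raw UMI count tables, 1 per library of 192 wells, without normalization and without pooling of replicates. Per the submitters' processing notes, bcl2fastq 2.15.0.4 and the genome build mm9 were used. The aligner and the counting tool are not given in the sources used here. The deposited cell table gives the sequencing batch, the plate position, the count of reads and the count of genes for each of 14400 wells, in 27648 lines. Its gene number was checked and equals that of the count tables in all 14400 wells. 4 further columns of that table were not used. Tables held 33924 gene rows and 92 spike-in rows. The 37 mitochondrial rows were 0 throughout, so a limit of 20% mitochondrial UMIs removed 0 cells.

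Libraries were grouped by the deposited stage labels. The labels give 43 embryo and 32 culture libraries in 12 groups, while the design text speaks of 41 and 34 and of other numbers per stage, and the labels were followed. Titles number the libraries in 1 series over all groups, and no label ties a library to an embryo or a culture. Cells with at least 1000 UMIs were kept, 13015 in all. Kept cells per library numbered 76 to 192, and median UMIs per kept cell 2041 to 15225. No doublet caller was run, since cells were sorted 1 to a well.

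Groups, comparisons, gene lists and alternatives were fixed before the data were examined. UMI counts of the kept cells were summed per library. One edgeR 4.0.16 model was fitted to the 43 embryo libraries (13221 genes, common biological coefficient of variation 0.430, 39 residual degrees of freedom) and 1 to the 32 culture libraries (12460 genes, 0.464, 24). Genes were filtered by filterByExpr with the groups, libraries scaled by TMM, and the robust quasi-likelihood F test used. P-values were adjusted by Benjamini-Hochberg at 0.05 over all genes tested in a comparison. CPM values are those of edgeR after TMM scaling, as mean ± SD over libraries. Which members of the gene lists are named was settled after their values were seen. For 1 gene counted among the named genes in the alternatives, the result is not reported here. Log2 changes come from the model, with their standard error (SE). The organoid side of its comparison with nEnd is the mean of the 3 organoid coefficients. A gene with no count in 1 group was given a least fold against a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with a 95% counting interval.

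Lists were tested with camera of limma 3.58.1, with the preset correlation of 0.01 between genes and again with an estimated correlation, and with fry. 37 lists of 6 to 25 genes were written from general knowledge, with 468 genes, of which 466 had a row. Camera p-values were adjusted over the lists of a comparison. Genes of a list were also adjusted over the list alone.

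The text names, for each comparison, the 8 genes with the largest and the 8 with the smallest log2 change among genes past the threshold with a mean of at least 50 CPM in the higher group. It also names up to 4 members of each list with the smallest adjusted p, members needed to describe a list, and the sort genes Foxa2, Gsc, Hhex, Cdh1 and Cxcr4.

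Embryo cells were clustered in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0. Cells were scaled to 10000 UMIs, 2000 variable genes and 30 principal components were used, and a graph of 15 neighbours was split by Leiden (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. A cluster took a class name when at least 3 markers of the class were raised (log2 difference of at least 1, at least 20 CPM). The marker genes define the visceral endoderm-like class, so their presence in it is no finding. The same holds for gut tube, foregut, hindgut and definitive endoderm markers in the definitive endoderm or gut-like class. Classes were summed per library where at least 10 cells were present, and fitted for visceral endoderm-like cells (16 libraries, 5957 genes, coefficient of variation 0.253) and for definitive endoderm or gut-like cells (37 libraries, 11006 genes, 0.329). Shares of cells were compared between stages by permutation of libraries (100000 resamples, or exact), two-sided, with adjustment over 3 comparisons. Similarity is Spearman's correlation of log2(CPM + 1) over genes with a mean of at least 10 CPM.

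After the data were seen, a signature of the arm was built from 16 rows high in culture and 7 high in embryos, with nEnd and organoid libraries against E8.5 libraries as references. Each row had at least 20 CPM in each reference library of its arm and a log2 difference of at least 3. Dependence of cells on the plate row was tested by 100000 permutations on 10 principal components, and 44 of 75 libraries passed an adjusted p of 0.05. No library was moved to another label. Neighbouring libraries of a label and sequencing batch were taken as like when they fill the 2 complementary well sets of a plate layout under successive title numbers, or when their chi-square per degree of freedom over genes lay under 5.5, a limit set after the values were seen. This gave 26 pairs, at 1.94 to 6.50.

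Tests were tried on simulated data with known changes. Changed genes were drawn from those with a mean of at least 50 CPM. Simulated libraries were independent, without batches, like neighbours or cells of the other arm. The recovered shares therefore do not hold for lower genes, and may be too high for the real libraries. Of 100 genes changed 2-fold, 93% were recovered between E7.5 and E6.5, 98% between E8.5 and E7.5, 38% between E9.5 and E8.5, 6%, 5% and 13% in the steps to Day4, Day5 and Day6, 48% between nEnd and Day6 and 22% between organoids and nEnd. Of genes changed 4-fold, 66%, 63% and 82% were recovered in the steps to Day4, Day5 and Day6, and at least 95% in the other 5.

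Alternatives were RLE size factors, DESeq2 1.42.0, limma-trend with cells scaled equally, other limits on genes and cells, ribosomal genes left out, sequencing batch as a covariate, a fit of the compared groups alone, other cluster resolutions and each library of small groups left out. Added after the data were seen were own-arm cells, libraries left out by signature, Hox level or plate rows, sums of like neighbours, tests within a batch, and for the difference between classes a fit with library as a block. R 4.3.3 and matplotlib 3.10.9 were used. The supplied reference is of a later build than mm9, so no genome position is printed. Values rest on gene names as deposited.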

Results

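MARS-seq counts unique molecular identifiers (UMIs) at the 3′ ends of transcripts in single cells sorted into plate wells. It was applied to mouse embryos with a Foxa2-Venus reporter and to embryonic stem cells led towards endoderm in culture. Foxa2 is a forkhead factor of the anterior primitive streak, the node, the notochord and the endoderm. Embryo cells were selected for Venus. Cultured cells were selected on Gsc-GFP with Hhex-RedStar, or on E-cadherin with Cxcr4. Of 14400 wells in 75 libraries, 13015 held at least 1000 UMIs, 7655 in 43 embryo libraries and 5360 in 32 culture libraries. The stage labels give 11 libraries at E6.5, 14 at E7.5, 15 at E8.5 and 3 at E9.5. The culture labels give 2 at Day3, 4 at Day4, 2 at Day5, 14 at Day6, 4 of naive endoderm (nEnd) and 2 each of organoids named Org_2, Org_3 and Org_5. Kept cells of a library summed to between 379955 UMIs (an Org_5 library) and 3052377 UMIs (an E6.5 library). P-values measure only the spread between libraries, because the labels do not tie libraries to embryos or cultures. Each library counts as a replicate, although 26 pairs of neighbours, 20 of them on the 2 complementary well sets of a plate layout with successive title numbers, had like RNA, so n may overstate the independent samples. With these pairs summed 6 libraries are left at E6.5, 7 at E7.5, 12 at E8.5, 2 at E9.5, 1 at Day5, 10 at Day6, 2 of nEnd and 1 of each organoid name. Counting intervals cover counting error only.

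Several libraries held cells whose RNA matched another label, and all comparisons keep the labels as deposited. A set of 23 ribosomal protein and pseudogene rows separated embryo from culture cells, and 12 libraries had over 10% of cells with the signature of the other arm. E7.5 libraries 5 and 6 held 97.8% and 97.1% of such cells, and Day6 libraries 3 and 4 held 100% and 98.9%. E7.5 libraries 7 and 8 held 78.1% and 77.8%, and E6.5 libraries 8 and 9 held 66.8% and 67.96%. In these last 2 pairs they lay in blocks of plate rows, as the map of plate rows shows. The E7.5 means include these cells. Of the kept cells of E7.5 libraries 7 and 8, 77.0% and 71.7% fell in the anterior visceral endoderm-like class. E7.5 libraries outside 5 to 8 had at most 4.23% there. The summed Hox level of E6.5 libraries 5, 6, 7, 10 and 11 lay above that of each E7.5 library, which reached at most 141 CPM. Only E6.5 libraries 3 and 4 showed neither feature.

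**Figure D1:**
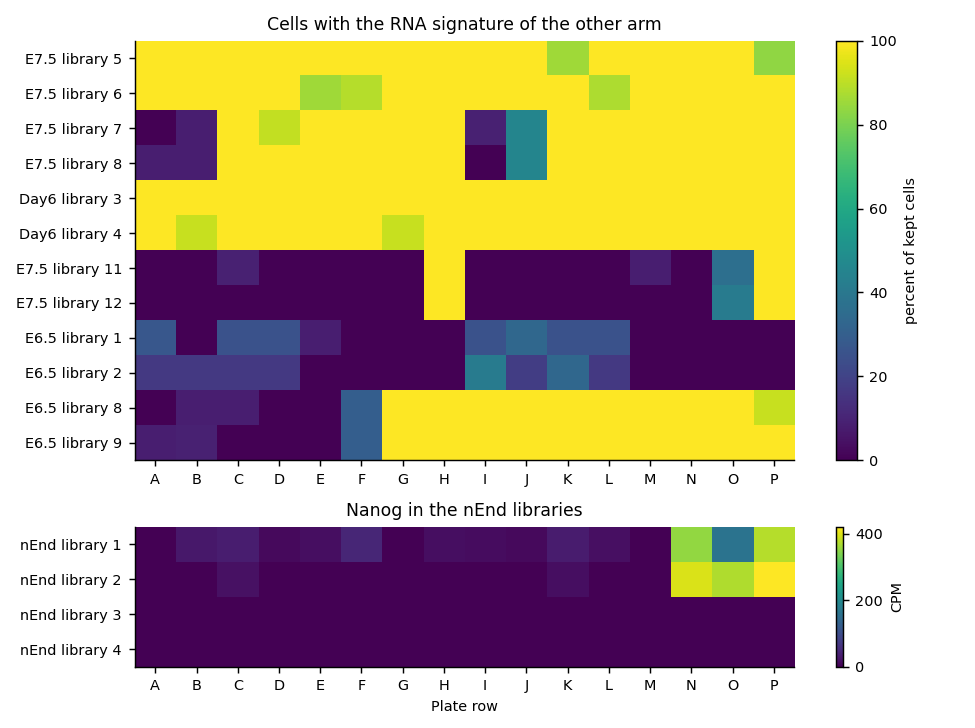
Percent of kept cells with the RNA signature of the other arm, by plate row, in the 12 libraries with over 10% of such cells, and Nanog in CPM by plate row in the 4 nEnd libraries. Nanog in nEnd libraries 1 and 2 lies mostly in rows N to P, with 92.4% of its UMIs.

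**Figure D2:**
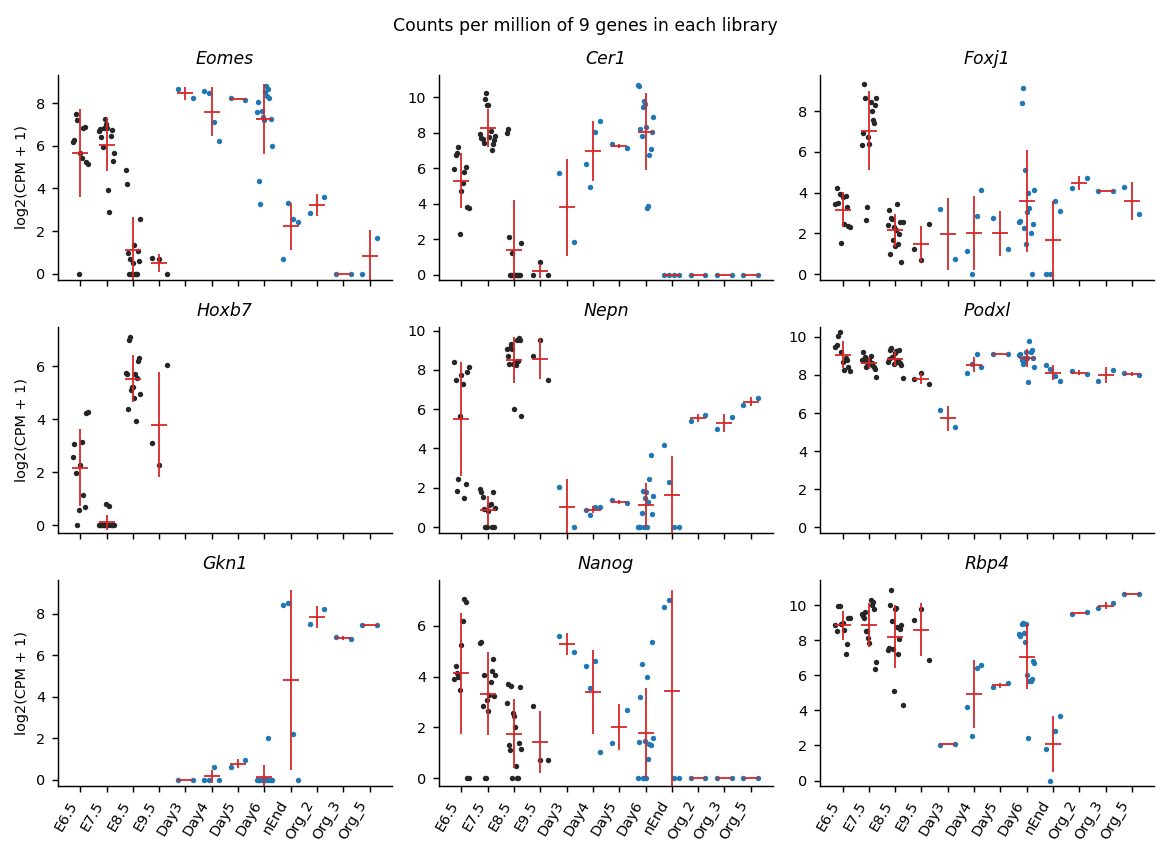
Log2(CPM + 1) of 9 genes, 1 point per library, with the mean and SD of the libraries of a label as bars (black, embryo; blue, culture). A label without points belongs to an arm in which the gene was too low to be tested, and Cer1 is at 0 in all 4 nEnd libraries.

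E7.5 was compared with E6.5 to see what gastrulation adds to Foxa2-positive cells. Foxj1, the regulator of motile cilia in the node, stood at 223 ± 179.7 against 9.28 ± 5.12 CPM (mean ± SD, n = 14 and 11; log2 change 4.56, SE 0.50, adjusted p = 1.55e-08). T, which drives streak and notochord formation, rose from 51.8 ± 53.8 to 586 ± 359 CPM (log2 change 3.51, SE 0.58, adjusted p = 3.62e-05). Chrd, a BMP antagonist made by the node, rose from 5.96 ± 2 to 73.6 ± 54.5 CPM (log2 change 3.60, adjusted p = 2.57e-08). Mesp1 and Tbx6, factors of nascent and presomitic mesoderm, reached 51.4 ± 46.2 and 49.9 ± 46.3 CPM from 1.73 ± 3.7 and 2.5 ± 2.62 (adjusted p = 7.28e-06 and 2.86e-06). The other genes with the largest rise were Dynlrb2, 1110017D15Rik, 1700027A23Rik, Gal, Tppp3 and 1700009P17Rik, with log2 changes from 4.70 (1700009P17Rik) to 7.78 (Dynlrb2). Trh and Lefty2 rose by log2 changes of 3.20 and 4.28 (adjusted p = 0.000135 and 0.000689), and the Wnt targets Lef1 and Sp5 by 1.75 and 1.67 (adjusted p = 0.000297 and 0.00361).

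Other genes were higher in libraries labelled E6.5. Nepn, a secreted protein of gut endoderm, stood at 133 ± 127 CPM against 1.05 ± 1.009 at E7.5 (log2 change -6.70, SE 0.77, adjusted p = 4.09e-08). The plasma protein genes Itih2, Serpina1b, Ambp and Apoa2, made by liver and visceral endoderm, changed by log2 values from -8.20 (Itih2, adjusted p = 0.00052) to -2.65 (Apoa2, adjusted p = 0.00829). Serpina1b has near-identical neighbours, so its level is uncertain. Arg1 (log2 change -3.68), Dlk1 (-3.09), Afp (-1.98), Sox2 (-2.49) and the pluripotency gene Dppa5a (-3.74) fell too. Dppa5a lost its call with own-arm cells only, without libraries of the other arm's signature, without libraries of over 25% variance between plate rows, without either kind of doubted library, with batch as a covariate, within batch 13, with limma-trend and with like neighbours summed. Klf2, a gene of naive pluripotent cells, fell from 41.8 ± 72.4 to 5.29 ± 3.28 CPM (adjusted p = 0.00212) but turned to 0.29 on the log2 scale without libraries of the other arm's signature. Cer1 rose from 58.1 ± 47.1 to 407 ± 355 CPM (adjusted p = 0.0457), a call that DESeq2 did not share and that turned to -0.90 with batch as a covariate. Hoxb7 had 2 UMIs over the E7.5 libraries and was 57.6-fold (counting interval 15.6 to 481) higher at E6.5, and Hoxc4 changed by -4.50 on the log2 scale. Without either kind of doubted library 8 against 2 are left, the E6.5 side a pair of like neighbours. There Ambp, Arg1, Dlk1, Itih2 and Serpina1b no longer fell: their log2 values turned to 0.15, 2.90, 0.26, 0.58 and 0.69. Foxa2 rose from 119.9 ± 13.8 to 159.6 ± 30.4 CPM (adjusted p = 0.015). This call was lost with sequencing batch in the model, with limma-trend, with like neighbours summed and within batch 13. It was also lost without libraries of over 25% variance between plate rows, without the Hox-high E6.5 libraries and without either kind of doubted library. Gsc, Hhex, Cdh1 and Cxcr4 did not pass the threshold (adjusted p = 0.488, 0.389, 0.113 and 0.0682). With own-arm cells only Gsc passed as a fall (log2 change -2.51, adjusted p = 0.00287), against 0.81 with all cells, as did Hhex (0.0188), and Cdh1 passed as a rise (0.0219). Within batch 13 Gsc (-3.84, edgeR adjusted p = 1.29e-06) and Hhex (3.05e-05) passed as falls and Cdh1 (3.45e-08) and Cxcr4 (0.00724) as rises.

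Of 13221 genes tested between E7.5 and E6.5, 1569 passed an adjusted p of 0.05, with 914 higher and 655 lower at E7.5. Of the 10 node and notochord markers tested, 8 rose (9 adjusted over the list alone; camera adjusted p = 5.2e-12), and this call held with an estimated correlation (0.0415). Of 9 mesoderm markers 4 rose (6 adjusted over the list alone; adjusted p = 0.000452), and of 13 Wnt target genes 6 rose (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.0022). Of 22 Hox genes 19 fell (19 fell and 1 rose adjusted over the list alone; adjusted p = 4.07e-13), and of 10 liver markers 7 fell (9 adjusted over the list alone; adjusted p = 0.000701). Of 9 naive pluripotency markers 7 fell (8 adjusted over the list alone; adjusted p = 0.00482). Of 17 glycolysis genes 4 fell, Pdk1 among them (log2 change -1.28; list adjusted p = 0.00327). The calls of these mesoderm, Wnt, Hox, liver, naive and glycolysis lists were lost with an estimated correlation (adjusted p = 0.0906, 0.408, 0.203, 0.408, 0.408 and 0.408). Within sequencing batch 13 (2 against 2 libraries, each side a pair of like neighbours and the E6.5 pair among those with high Hox) 1303 genes passed, 503 of them also in the full comparison, and with batch as a covariate 320 passed. Of 31 named genes with a call, 13 kept it with batch as a covariate and 14 without either kind of doubted library, with Mesp1, Lefty2 and Sox2 among those lost in both. Summing like neighbours left 498 genes, and 21 of the 31 kept their call. Without libraries of over 25% variance between plate rows 13 of the 31 did, with T, Gal, Trh and Sp5 among those lost, and Nepn was lost without either kind of doubted library. Without either kind of doubted library the Hox list did not pass and lay in the other direction (camera adjusted p = 0.822). Without libraries of the other arm's signature 947 passed, and 1827 without either kind of doubted library, of which 615 passed in both and 13 of these in opposite directions. Once both kinds are left out the E6.5 side is a pair of like neighbours, so no spread between E6.5 samples enters.

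The comparison of E8.5 with E7.5 follows Foxa2-positive cells from gastrulation to the gut tube, notochord and floor plate. Hox genes, which set position along the trunk, came on. Hoxa7 rose from 0.511 ± 0.639 to 63.9 ± 36 CPM (n = 14 and 15; log2 change 6.80, SE 0.59, adjusted p = 4.7e-11). Hoxb7 had 2 UMIs at E7.5 and was 542-fold (counting interval 149.8 to 4479) higher at E8.5, and Hoxc8 had 1 UMI at E7.5 and was 472-fold (counting interval 84.5 to 18684) higher. Nepn rose from 1.05 ± 1.009 to 443 ± 227 CPM (adjusted p = 1.69e-10). The floor plate and ventral neural factors Nkx2-9 and Nkx6-1 rose to 98 ± 85.4 and 91.7 ± 72.1 CPM from 1.25 ± 1.28 and 4.77 ± 3.55 (adjusted p = 2.24e-05 and 0.00027). Cdx2, which patterns the hindgut, rose from 15.4 ± 11.8 to 52.4 ± 42.7 CPM (adjusted p = 0.000782). Sox2, Foxa1, Hoxb4, 2700086A05Rik and Olfml3 also rose, by log2 changes of 3.001, 1.26, 4.54, 9.12 and 5.10. The embryonic globin genes Hbb-y and Hba-x were called higher (at least 394-fold for Hbb-y, over the floor of 3 counts in the group), but most of their counts came from E8.5 library 7, and DESeq2 and limma-trend did not call them.

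Foxj1 fell over the same interval from 223 ± 179.7 to 4.07 ± 2.62 CPM (log2 change -5.78, SE 0.48, adjusted p = 2.51e-11). Mesp1 stood at 0.567 ± 1.39 against 51.4 ± 46.2 CPM (adjusted p = 2.22e-08), Lhx1, a factor of the anterior streak and node, at 8.94 ± 16.5 against 402 ± 414 CPM (adjusted p = 2.75e-07), and Eomes, which specifies mesoderm and endoderm, at 3.68 ± 8.01 against 83.4 ± 43.4 CPM (adjusted p = 9.59e-07). The Nodal antagonists Lefty1 and Lefty2 changed by log2 values of -5.35 and -5.94, Pga5 by -5.26 and 1110017D15Rik by -5.01. Tdgf1, Otx2, Cer1, Trh and Chrd changed by -3.87, -2.81, -3.46, -2.68 and -2.79 on the log2 scale, and the epiblast genes Fgf5 and Dnmt3b by -4.26 and -1.85. Gsc and Cdh1 fell (log2 change -3.83 and -1.17; adjusted p = 9.96e-05 and 8.47e-06), as did Cxcr4 (-1.002; adjusted p = 0.0222), while Foxa2 and Hhex did not pass (adjusted p = 0.363 and 0.18). Without the libraries of the other arm's signature Gsc, Cer1, Lefty1, Otx2, Pga5 and Hbb-y lost their calls and Cxcr4 turned to 0.13 on the log2 scale, and with own-arm cells only Gsc, Lefty1, Pga5 and Cxcr4 lost theirs. Lefty1, Gsc, Pga5 and Cxcr4 turned to 2.29, 0.38, 0.35 and 0.30 with batch as a covariate. In sequencing batch 3 the E8.5 side is libraries 1 and 2, a pair of like neighbours, so no spread between E8.5 samples enters. They hold 31.1% and 32.1% definitive endoderm-like and 16.3% and 15.8% parietal endoderm-like cells, against at most 2.63% and 0.53% in the other E8.5 libraries. There, against 4 E7.5 libraries, Lefty1, Pga5, Fgf5, Cxcr4, Cer1, Dnmt3b, Otx2, Cdh1 and Gsc did not fall (log2 change 1.80, 1.80, 0.95, 0.53, 0.52, 0.51, 0.053, 0.0076 and 0.0066), and Pga5 passed in the opposite direction (edgeR adjusted p = 6.94e-06), as did Dnmt3b and Fgf5 (0.048 and 0.0498), Hhex (log2 change 1.002; 0.0213), which had no call in the full comparison, and the anterior visceral endoderm markers as a list (camera adjusted p = 3.51e-06).

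Of 13221 genes tested between E8.5 and E7.5, 3363 passed, 1594 higher and 1769 lower at E8.5. All but 1 of the 22 Hox genes tested rose (camera adjusted p = 3.97e-40; 0.00352 with an estimated correlation), as did 7 of 8 hindgut markers (6.34e-12; 0.0204 with an estimated correlation), with the same counts adjusted over the list alone. Of 16 gut tube markers 8 rose and 2 fell (10 and 3 adjusted over the list alone; adjusted p = 0.000359), and 7 of 9 floor plate markers rose (0.000103). The S-phase genes rose in 9 of 16 cases, Mcm6 and Rrm2 among them (11 adjusted over the list alone; adjusted p = 1.08e-06). Epiblast markers fell in 6 of 8 cases (0.00026; 6 fell and 1 rose adjusted over the list alone), primitive streak markers in 6 of 10 (0.000359; 7 adjusted over the list alone) and anterior visceral endoderm markers in 4 of 7 (0.00026). The calls of the gut tube, floor plate, S-phase, epiblast, streak and anterior visceral endoderm lists were lost with an estimated correlation (adjusted p = 0.174, 0.189, 0.241, 0.159, 0.174 and 0.174). Within sequencing batch 3 (2 against 4 libraries) 686 genes passed, and 236 with batch as a covariate. Within batch 3 the floor plate and epiblast lists lay in the other direction, without a call (camera adjusted p = 0.761 and 0.253). The anterior visceral endoderm list did so with a call (3.51e-06). Of 34 named genes with a call, 11 kept it with batch as a covariate, with Eomes, Lhx1, Cdx2 and Nkx6-1 among those lost. The sums of like neighbours gave 2140 genes, and 32 of the 34 kept their call.

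E9.5 was compared with E8.5 for the onset of organ programmes in the gut and liver. Ghrl, the ghrelin gene of gut endocrine cells, rose from 7.78 ± 20.2 to 258 ± 232 CPM (n = 15 and 3; log2 change 5.01, SE 0.95, adjusted p = 0.00838). Serpinf2, a plasma protease inhibitor from liver, rose from 11.7 ± 14.1 to 85.6 ± 37.4 CPM (adjusted p = 0.0458), and Rian, an imprinted noncoding RNA, from 20.7 ± 8.32 to 77.4 ± 17.6 CPM (adjusted p = 0.0199). Eps8l2 and Gm10925 rose, and so did Hist2h2ac, Hist1h1b and Hist1h4d, histone genes with near-identical copies and so uncertain. Slc2a1, the glucose transporter of early embryos, fell from 1248 ± 433 to 313 ± 87.9 CPM (log2 change -1.997, SE 0.46, adjusted p = 0.0301). Lin28a, which holds back let-7 maturation, fell from 432 ± 103 to 171 ± 19.2 CPM (adjusted p = 0.044). Cthrc1, Vangl1, Ptplb, Laptm4a, Tmem88 and Cisd1 fell by log2 changes from -2.50 (Cthrc1) to -1.26 (Cisd1), and the replication genes Mcm4 and Mcm7 by -1.11 and -0.78. The liver factor Prox1 and Serpina1b did not pass (log2 change 2.81 and 3.19; adjusted p = 0.0991 and 0.119), nor did Lss of sterol synthesis, or the sort genes Foxa2, Gsc, Hhex, Cdh1 and Cxcr4 (adjusted p between 0.151 and 0.768).

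Of 13221 genes, 91 passed between E9.5 and E8.5, 58 higher and 33 lower at E9.5, with 2122 at an unadjusted p under 0.05. All 10 liver markers lay higher, none past the threshold (6 adjusted over the list alone; camera adjusted p = 2.07e-06), and so did all 16 cholesterol synthesis genes (5 adjusted over the list alone; adjusted p = 1.2e-05). Of 16 S-phase genes 2 fell (5 adjusted over the list alone; adjusted p = 1.45e-06), and of 15 FGF and ERK response genes none passed (2 fell adjusted over the list alone; adjusted p = 2.83e-05). The 4 calls were lost with an estimated correlation (adjusted p = 0.253, 0.334, 0.331 and 0.0729). The count rested on single libraries: 7 genes passed without E9.5 replicate 1, 6 without replicate 2 and 228 without replicate 3. Within sequencing batch 7 (2 against 2, each side a pair of like neighbours) 271 passed, Cdh1 among them as lower (edgeR adjusted p = 0.0082), and 0 with batch as a covariate. Of 18 named genes with a call, 1 kept it without replicate 1, 0 without replicate 2 and 14 without replicate 3. Only 3 genes passed with like neighbours summed (2 against 12), and none of the 18 kept its call.

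Visceral endoderm, the extraembryonic layer that feeds the early embryo and mixes into the gut, was followed as a share of cells. Cells of 1 cluster with 17 of 18 visceral endoderm markers raised made up 10.5 ± 15.6% of kept cells at E6.5 (SD, n = 11), 9.08 ± 7.13% at E7.5 (n = 14), 3.12 ± 3.64% at E8.5 (n = 15) and 0.355 ± 0.614% at E9.5 (n = 3). The share fell from E7.5 to E8.5 (difference -5.96 points, permutation p = 0.00872, adjusted p = 0.0262, two-sided), while no difference was called between E7.5 and E6.5 (difference -1.39 points, permutation p = 0.759). The E6.5 mean rests on libraries 3 and 4, the only 2 not in doubt, at 41.6% and 41.4%, with the other 9 at 0% to 10.5%. Against these 2 alone the 8 E7.5 libraries not in doubt lay lower, short of the threshold (difference -30.4 points, exact p = 0.0444, adjusted p = 0.0667). E6.5 libraries 3 and 4 are a pair of like neighbours, and the 8 E7.5 libraries lie in such pairs too. No spread between E6.5 samples thus enters that test. With own-arm cells only the difference was 2.05 points, so the comparison of E7.5 with E6.5 depends on which libraries are kept. No difference was called between E9.5 and E8.5 (difference -2.77 points, exact p = 0.211, adjusted p = 0.316). The fall to E8.5 did not pass with like neighbours summed (difference -6.14 points, exact test, adjusted p = 0.0955). With like neighbours kept apart it passed with own-arm cells only, from 13.2% to 3.14% (-10.05 points, permutation test, adjusted p = 0.00024). It also passed without libraries of the other arm's signature (-7.92 points, exact test, adjusted p = 0.00664). The Foxa2-Venus sort sets which cells enter these shares. An anterior visceral endoderm-like cluster with 10 of the 18 markers raised holds 443 of its 484 cells in E6.5 libraries, and with it counted the E6.5 share was 31.8 ± 30.9% and the drop to E7.5 passed (difference -22.4 points, permutation test, adjusted p = 0.0157).

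**Figure D3:**
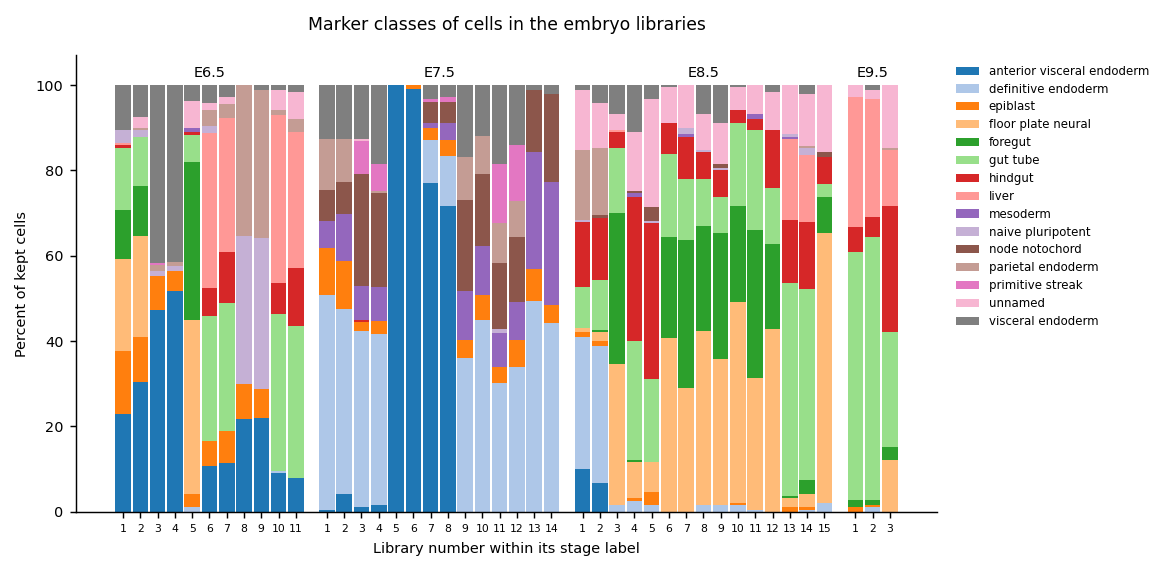
Percent of kept cells in each marker class, 1 bar per embryo library, grouped by stage label. Visceral endoderm-like cells average 9.08% at E7.5 and 3.12% at E8.5. E7.5 libraries 7 and 8, with mostly cells of the culture signature, have 77.0% and 71.7% in the anterior visceral endoderm-like class.

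Within visceral endoderm-like cells, E7.5 was compared with E6.5 to see how this layer matures (8 and 4 libraries). Fxyd2, a subunit of the sodium pump, rose from 44.2 ± 17 to 184 ± 54.5 CPM (log2 change 2.10, SE 0.26, adjusted p = 3.13e-06). Rbp4, which carries retinol, rose from 1480 ± 111 to 3991 ± 976 CPM (adjusted p = 3.13e-06). Dlk1, a paternally expressed Notch ligand homologue, rose from 113 ± 40.9 to 435 ± 34.7 CPM (adjusted p = 5.05e-08), and T from 1.43 ± 2 to 32.4 ± 9.52 CPM (adjusted p = 0.000594). Anxa6, Plbd1, Dusp9, Gatsl2, Lgals2 and S100a1 rose by log2 changes from 1.48 (S100a1) to 2.52 (Anxa6). The streak genes Mixl1, Eomes and Wnt3 fell, Mixl1 from 75.3 ± 20.1 to 8.06 ± 6.78 CPM (adjusted p = 0.000244), and so did Utf1 and Dppa5a of pluripotent cells, the DNA methyltransferase gene Dnmt3b (954 ± 61.3 to 425 ± 108 CPM, adjusted p = 0.000152), Mest, Srgn, Gpc4 and Mt2. Foxa2 and Cdh1, the only sort genes measured well enough here, did not pass (adjusted p = 0.935 and 0.833).

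Of 5957 genes 71 passed in this class, 46 higher and 25 lower at E7.5. Of 17 visceral endoderm markers 3 rose (6 adjusted over the list alone; camera adjusted p = 1.72e-05; 0.0443 with an estimated correlation), and 1 of 14 lipid transport genes (6 adjusted over the list alone; 3.16e-06; 0.0167). Of 5 streak markers 3 fell and T rose (1.72e-05; 0.00464). Without E6.5 replicate 3 the count was 32 and without replicate 4 it was 46, and with like neighbours summed (4 against 2) it was 23. Without libraries of the other arm's signature 16 genes passed, and Anxa6, Gatsl2, Lgals2, S100a1, Utf1, Wnt3, Eomes, Dppa5a, Srgn, Gpc4, Dnmt3b and Mt2 lost their calls.

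The same class was compared between E7.5 and E8.5 (8 and 4 libraries). Ttr, which carries thyroid hormone, rose from 8906 ± 1038 to 16240 ± 3056 CPM (log2 change 0.87, SE 0.12, adjusted p = 8.71e-05). Trf, the transferrin gene, rose from 351 ± 54.1 to 776 ± 217 CPM (adjusted p = 8.71e-05), Spp2 from 194 ± 39.8 to 566 ± 232 (adjusted p = 8.71e-05), Apoa2 from 128 ± 60.7 to 569.8 ± 118 (adjusted p = 0.00249) and Rbp4 from 3991 ± 976 to 7400 ± 1473 (adjusted p = 0.00236). Afp, Apoa4, Cfi, Bmp7, Crip1, Ptpmt1 and Tmem79 also rose (log2 changes 0.77 to 1.70). Msx2, a target of BMP signals, fell from 90.7 ± 33.1 to 20.9 ± 11.7 CPM (adjusted p = 0.00249), Dnmt3b from 425 ± 108 to 186 ± 67.5 CPM (adjusted p = 0.00249) and the glycolytic gene Pkm2 from 1400 ± 286 to 838 ± 189 CPM (adjusted p = 0.0158). Srgn, Dvl2, Plac1, Car2, Uck2, Itsn1 and Cldn19 fell by log2 changes from -3.30 (Srgn) to -1.18 (Cldn19). Foxa2 and Cdh1 did not pass (adjusted p = 0.947 and 0.854). Of 5957 genes 59 passed, 44 higher and 15 lower at E8.5. Of 17 visceral endoderm markers 6 rose (8 rose and 1 fell adjusted over the list alone; camera adjusted p = 9.46e-08; 0.0263 with an estimated correlation), and of 14 lipid transport genes 5 rose (7 rose and 1 fell adjusted over the list alone; 9.46e-08; 0.0234). Of 14 glycolysis genes 1 rose and 1 fell (1 and 6 adjusted over the list alone), a call for lower levels (0.00184; 0.0286). The count was 17 without E8.5 replicate 3, 22 without replicate 4 and 34 without replicate 8, and 4 with clusters drawn at a Leiden resolution of 2, where Ttr, Rbp4, Apoa2, Apoa4, Afp, Spp2 and Cfi lost their calls. Afp, Apoa4 and Cfi also lost theirs without E8.5 replicate 3 or 4 and with like neighbours summed (3 against 4), where 24 genes passed.

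Definitive endoderm or gut-like cells were also compared between E7.5 and E8.5 (12 and 15 libraries). Most E7.5 cells of this class lie in clusters named by definitive endoderm markers and most E8.5 cells in clusters named by gut tube, foregut or hindgut markers, so changes of these markers, Nepn, Pyy, Cdx2, Krt7, Krt19, Hoxc8, Hoxc9, Trh and Cer1 among them, follow in part from the naming. Nepn rose from 1.55 ± 2.43 to 790.4 ± 332 CPM (log2 change 8.56, SE 0.56, adjusted p = 4.28e-13). Cxcl12, a chemokine, had 1 UMI at E7.5 and was 774-fold (counting interval 139 to 30594) higher at E8.5, and Pyy, a gut hormone gene, had 3 UMIs and was 408-fold (counting interval 139 to 1980) higher. Hoxb7 and Hoxc9 had no UMI at E7.5 and were at least 186-fold and at least 133-fold higher at E8.5, over the floor of 3 counts in the group. Hoxb6, Hoxc8, Hoxa7 and 2700086A05Rik, with 1 to 3 UMIs at E7.5, stood at 73 ± 53.7, 37.2 ± 26.1, 98.3 ± 47.1 and 227 ± 131 CPM at E8.5. Cdx2 rose from 10.8 ± 7.17 to 72.2 ± 51.1 CPM (adjusted p = 9.81e-07), and the keratins of simple epithelia Krt7 and Krt19 rose by log2 changes of 1.40 and 1.45. Trh, a hormone precursor made by early definitive endoderm, fell from 1095 ± 472 to 128 ± 138 CPM (log2 change -3.14, SE 0.57, adjusted p = 0.000105). Lhx1, Tdgf1 and Fgf5 changed by -5.16, -5.11 and -3.20 on the log2 scale, Fmr1nb and Prss12 by -3.48 and -3.19, and Gm7638 and Gm10263, uncertain where reads are shared with copies, by -6.06 and -3.40. Amn, Apoe and Apoa1, used by visceral endoderm for uptake and lipid carriage, fell as well (Amn 126 ± 44.3 to 16.2 ± 14.4 CPM, adjusted p = 1.12e-07), as did Foxj1, Chrd, Otx2 and Cer1. Cluster 11 of this class had 6 of 18 visceral endoderm markers raised. It gave 235 of the 739 E7.5 cells but 25 of the 1494 E8.5 cells. A fall of visceral endoderm genes in the class cannot be told apart from the loss of this cluster. Foxa2 fell from 212 ± 39.9 to 115 ± 32.4 CPM (adjusted p = 1.67e-06) and Cdh1 from 464 ± 50.6 to 240.2 ± 73.4 (adjusted p = 4.66e-07), while Gsc, Hhex and Cxcr4 did not pass (adjusted p = 0.0501, 0.316 and 0.55).

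Of 11006 genes 2264 passed in definitive endoderm or gut-like cells, 1307 higher and 957 lower at E8.5. Clusters 2 and 11 held most of this class at E7.5, and clusters 1, 3, 5 and 9 at E8.5. After like neighbours were summed 1511 genes passed, and all 29 named genes with a call kept it. All 22 Hox genes rose (camera adjusted p = 6.73e-33; 0.00125 with an estimated correlation), 4 of them hindgut markers that name clusters. The hindgut and gut tube lists are not read here, since they name the clusters of most E8.5 cells. Node and notochord markers fell in 8 of 10 cases, with 1 higher (7.88e-07; 0.00125), epiblast markers in 5 of 6 (6 adjusted over the list alone; 7.06e-07; 0.00183) and anterior visceral endoderm markers in 6 of 7 (8.45e-06; 0.0422). Cer1 and Hhex of the anterior list are also definitive endoderm markers. Cluster 2, with 503 of the 739 E7.5 cells, had 4 of the 7 anterior markers raised. The fall of this list thus follows in part from the naming. Visceral endoderm markers fell in 10 of 17 cases (12 adjusted over the list alone; 1.6e-10), a call lost with an estimated correlation (0.0658). This fall, too, cannot be told apart from the loss of cluster 11.

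In culture, Day4 was compared with Day3 for the step through the primitive streak. Podxl, a sialomucin of apical cell surfaces, rose from 54.1 ± 23.8 to 384 ± 114 CPM (n = 2 and 4; edgeR log2 change 2.82, SE 0.42, adjusted p = 0.00311) and was the only 1 of 12460 genes to pass. Sox17, a master factor of endoderm, stood at 191.9 ± 103 against 21.6 ± 13.8 CPM (log2 change 3.12, adjusted p = 0.282), Krt8 of simple epithelia at 804 ± 107.4 against 179.9 ± 69.2 CPM (0.282), the tight junction gene Cldn6 at 241 ± 224 against 18.6 ± 19.8 CPM (0.296), Col4a2 at 119.5 ± 42.3 against 27.2 ± 2.22 CPM (0.296) and the collagen chaperone Serpinh1 at 194 ± 66.9 against 75.8 ± 5.37 CPM (0.198). None of these passed, nor did Foxa2, Gsc, Hhex, Cdh1 or Cxcr4 (adjusted p between 0.446 and 0.882). All 17 epithelial junction genes lay higher at Day4 (0 passed, 8 adjusted over the list alone; camera adjusted p = 5.87e-09), as did all 10 definitive endoderm markers (0 passed, 1 adjusted over the list alone; 1.17e-05) and all 18 visceral endoderm markers (0 passed, 1 adjusted over the list alone; 0.000139). Of 13 basement membrane genes 10 lay higher (0 passed, 6 adjusted over the list alone; 2.84e-05), and this call alone held with an estimated correlation (0.0112; the others 0.228, 0.13 and 0.396). At an unadjusted p under 0.05 stood 1119 genes, and DESeq2 called 95. Without Day3 replicate 2 no gene passed, Podxl included, and without Day4 replicate 2 there were 4. With batch as a covariate 107 genes passed, 78 higher and 29 lower at Day4, Podxl among them, and with like neighbours summed elsewhere in the fit none did.

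Day5 and Day6 were each compared with the day before, to follow the passage to definitive endoderm. No gene passed with edgeR in either step, with 361 and 691 genes at an unadjusted p under 0.05. DESeq2 called 2 and 14, and limma-trend 0 and 0. From Day4 to Day5, Gpi1 of glycolysis stood at 348 ± 62.9 and then 586 ± 104 CPM (n = 4 and 2; log2 change 0.75, edgeR adjusted p = 1) and Dhcr7, the last enzyme of cholesterol synthesis, at 104 ± 35.9 and then 239.6 ± 2.59 CPM (log2 change 1.20, adjusted p = 1). Of 17 glycolysis genes 14 lay higher at Day5 (camera adjusted p = 0.00121) and of 16 cholesterol synthesis genes 15 (0.00296). From Day5 to Day6 both lists lay lower, with 14 of 17 glycolysis genes (3.65e-07; 3 fell adjusted over the list alone) and 15 of 16 cholesterol genes (2.25e-10) below their Day5 level, Tpi1 and Lss among them (log2 change -1.13 and -1.40). All 17 epithelial junction genes lay higher at Day6 (9.86e-07), with Krt19 at 193.4 ± 177 against 20.1 ± 4.49 CPM (n = 14 and 2; log2 change 3.25, adjusted p = 0.787), and so did 12 of 14 dissociation stress genes, Jun among them (6.42e-06; 7 rose and 1 fell adjusted over the list alone). Both steps share the same 2 like Day5 libraries, so opposite directions in them are not independent, and no value for unchanged groups was computed. The 6 list calls were lost with an estimated correlation (adjusted p between 0.264 and 0.917). With batch as a covariate the epithelial junction list at Day6 lay in the other direction, without a call (camera adjusted p = 0.527). Foxa2, Gsc, Hhex, Cdh1 and Cxcr4 passed in neither step (adjusted p = 1 at Day5 and between 0.787 and 0.962 at Day6). Within sequencing batch 15, 989 genes passed between Day5 and Day4 (2 against 1 library, so that the spread comes from 2 like Day5 libraries alone) and 403 between Day6 and Day5 (2 against 2, each side a pair of like neighbours). There Hhex (log2 change 2.72, edgeR adjusted p = 4.31e-10), Foxa2 (2.41e-08) and Gsc (0.000676) passed as higher at Day5 than at Day4, while Hhex lay lower in the full comparison (-0.87).

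Cells labelled naive endoderm (nEnd) were compared with Day6 definitive endoderm, to see how far these cultures differ. Col4a1 and Col4a2, basement membrane collagens that parietal endoderm secretes, stood at 5299 ± 2597 and 2346 ± 828 CPM against 272 ± 149 and 125 ± 73.2 at Day6 (n = 4 and 14; log2 change 4.28 and 4.22, edgeR adjusted p = 2.36e-11 and 2.44e-11). Sparc and Lamb1 of the same matrix rose to 3452 ± 749 and 2430 ± 617 CPM (adjusted p = 2.23e-09 and 6.92e-11). The naive pluripotency genes Dppa5a, Klf4 and Tcl1 were higher at 2128 ± 228, 203 ± 100.1 and 50.4 ± 25 CPM against 31.2 ± 50.5, 9.68 ± 8.32 and 0.18 ± 0.372 (adjusted p = 2.12e-07, 1.76e-08 and 7.74e-10). Gkn1, a stomach mucosa gene, stood at 179.6 ± 206 CPM (log2 change 9.02, adjusted p = 1.06e-08), and its neighbour in function Gkn2 had 3 UMIs at Day6 and was 1188-fold (counting interval 405 to 5771) higher. Gkn1 stood at 348 and 367 CPM in nEnd libraries 1 and 2 and at 3.63 and 0 in libraries 3 and 4, and against Day6 its call was lost with the latter pair alone. Vsig2, Fabp3-ps1 (a pseudogene, uncertain), Ramp1, Fam176a, Clic3 and Clps rose by log2 changes from 7.41 (Clps) to 8.32 (Vsig2). Clps lost its call with batch as a covariate and with nEnd libraries 1 and 2 alone. The lysosomal genes Ctsa and Ctsd and the metallothionein Mt1 rose as well, by 2.89, 2.42 and 4.22.

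Cer1, a secreted Nodal and BMP antagonist, had no UMI in nEnd and was at least 710.3-fold lower than at Day6 (530.0 ± 531 CPM), over the floor of 3 counts in the group. Gsc, the homeobox gene of the organizer, was at least 382-fold lower and Sfrp5, 1500016L03Rik, Coch and Shisa2 at least 287-fold, at least 176-fold, at least 139-fold and at least 83.6-fold lower. Fgf5 and Tspan7 had 1 and 2 UMIs and were 1337-fold (counting interval 239.8 to 52812) and 805-fold (counting interval 223 to 6649) lower. Lhx1, Eomes, Otx2 and Emb changed by -8.996, -5.61, -6.74 and -5.28 on the log2 scale, and Spry1 and Dusp6, feedback genes of FGF signalling, by -2.66 and -3.62. Cxcr4, on which cultured cells were sorted, stood at 1.22 ± 0.56 against 173 ± 80.4 CPM (adjusted p = 7.39e-08) and Hhex at 13.2 ± 5.8 against 99.4 ± 72 CPM (adjusted p = 0.00767), while Foxa2 and Cdh1 did not pass (adjusted p = 0.186 and 0.83). Cdh1 passed as higher with batch as a covariate (log2 change 3.296, edgeR adjusted p = 0.00276) and within batch 15 (3.13), where Foxa2 passed as lower (0.00973). The Hhex call was lost with batch as a covariate and with either pair of nEnd libraries alone.

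Of 12460 genes 4185 passed between nEnd and Day6, 2064 higher and 2121 lower in nEnd. Parietal endoderm markers rose in 8 of 10 cases (9 adjusted over the list alone; camera adjusted p = 9.88e-13; 0.000981 with an estimated correlation) and naive pluripotency markers in 9 of 10 (9.19e-07; 0.00671). In nEnd libraries 1 and 2 Nanog lay mostly in a block of plate rows: it stood at 339 CPM in rows N to P and 12.2 CPM in rows A to M. Basement membrane genes rose in 9 of 13 cases with 2 lower (10 and 2 adjusted over the list alone; 7.03e-11; 9.44e-05), and lysosome genes in 12 of 19 with 1 lower (13 and 1 adjusted over the list alone; 4.31e-10; 0.00934). Primitive streak markers fell in 8 of 10 cases (9 adjusted over the list alone; 1.29e-05; 0.0112), and FGF and ERK response genes in 7 of 14 with 1 higher (3.58e-05; 0.0201). Definitive endoderm markers fell in 8 of 10 cases with 1 higher (9.56e-05) and anterior visceral endoderm markers in 6 of 7 (0.00123), calls lost with an estimated correlation (adjusted p = 0.113 and 0.24). Within sequencing batch 15 (2 against 2 libraries, each side a pair of like neighbours) 4473 genes passed. Summed like neighbours (2 against 10) gave 2082, and 33 of 34 named genes kept their call, Hhex excepted.

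Organoids were compared with nEnd as another endoderm grown in culture. Rbp4 rose from 5.1 ± 5.17 to 1120 ± 399.6 CPM (n = 4 and 6; edgeR log2 change 7.77, SE 1.24, adjusted p = 0.000202). Apoa2, an apolipoprotein, had 1 UMI in nEnd and was 326-fold (counting interval 58.2 to 12913) higher. Nid1, which links laminin to collagen, rose from 12.9 ± 4.95 to 281 ± 127 CPM (adjusted p = 0.000268), the metalloprotease inhibitor Timp2 from 31.9 ± 27.1 to 304 ± 75.3 (adjusted p = 2.21e-05) and Serpinh1 from 916 ± 71.4 to 2691 ± 170.3 (adjusted p = 7.8e-05). Pdgfra, Sparc and Mttp rose by log2 changes of 1.64, 1.25 and 2.81 (adjusted p = 0.0221, 0.0411 and 0.0382), but Sparc and Mttp lost their calls without any 1 of the 10 libraries and Pdgfra without nEnd replicate 2, 3 or 4. Plac1 had 3 UMIs in nEnd and was 79.1-fold (counting interval 26.8 to 386) higher. Fgf3, Cfc1, Ctgf, Hexa and Emb rose by log2 changes from 1.78 (Hexa) to 4.22 (Fgf3), and Fgf3 lost its call without nEnd replicate 1, 2 or 4 and without 3 of the organoid libraries. Nanog, a core gene of pluripotent cells, had no UMI in organoids and was at least 117-fold lower than in nEnd, and Stmn2 at least 172-fold lower, over the floor of 3 counts in the group. Both nEnd libraries 3 and 4 had no Nanog either, and against these alone Aifm3 and Lamb3, which had 3 and 2 UMIs in organoids, no longer fell (log2 change 2.40 and 1.70). There 18 of 28 named genes kept their call, and Apoa2, Nt5e, Ube2c, Fgf3, Pdgfra, Sparc, Mttp and Nanog lost theirs too. Nt5e, Ccl17 and Rpl10l (a retrogene with copies, uncertain) had 1 to 2 UMIs in organoids, and Ifi27l1, Tcl1 and Esrrb changed by -7.59, -6.28 and -5.56 on the log2 scale.

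Glycolysis genes were lower in organoids. Hk2, which commits glucose to the pathway, stood at 41.8 ± 4.58 against 299.6 ± 142 CPM (log2 change -2.84, adjusted p = 5.92e-05), Gpi1 at 231 ± 58.3 against 697 ± 262 CPM (adjusted p = 0.000373) and Pkm2 at 349.6 ± 89.1 against 1004 ± 455 CPM (adjusted p = 0.00082). The mitotic genes Nusap1 and Ube2c and the FGF target Etv4 changed by -2.33, -1.41 and -2.43 on the log2 scale. Of 12460 genes 1626 passed, 432 higher and 1194 lower in organoids, and limma-trend split its 1155 calls into 583 and 572. Glycolysis genes fell in 11 of 17 cases (13 adjusted over the list alone; camera adjusted p = 3.53e-08) and G2 and M phase genes in 6 of 18 (12 adjusted over the list alone; 6.38e-05). Lipid transport genes rose in 4 of 14 cases (6 adjusted over the list alone; 4e-05), parietal endoderm markers in 2 of 10 (3 adjusted over the list alone; 0.000673) and lysosome genes in 4 of 19 (0.000673). The 5 calls were lost with an estimated correlation (adjusted p = 0.184, 0.445, 0.318, 0.191 and 0.233). Naive pluripotency markers fell in 4 of 10 cases (5 adjusted over the list alone) and FGF and ERK response genes in 6 of 14 with 1 higher (7 and 1 adjusted over the list alone), without a list call (adjusted p = 0.0622 and 0.0832). Foxa2, Hhex, Cdh1 and Cxcr4 did not pass (adjusted p = 0.197, 0.484, 0.103 and 0.784), and Gsc had 1 UMI in organoids and 0 in nEnd. In a fit of the compared groups alone Foxa2 passed as higher (edgeR adjusted p = 0.00457) and Cdh1 as lower (0.01), as they did within batch 21 (0.00123 and 0.00122). Without nEnd replicate 1 the count was 985 and without replicate 2 it was 1024. Within sequencing batch 21 (6 against 2 libraries, all in pairs of like neighbours) 3189 genes passed. With like neighbours summed (3 against 2) 131 passed, and 7 of 30 named genes kept their call, with Rbp4, Nid1, Nanog, Gpi1 and Pkm2 among those lost. The median log2 change of all genes was -0.15, against 0.02 in limma-trend. The organoid changes and counts were tested against 0 and are not corrected for this shift.

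Org_2, Org_3 and Org_5 were compared for any difference, since the labels do not explain their numbers. No gene passed edgeR's test over the 3 groups of 2 libraries, with 603 at an unadjusted p under 0.05, and no gene passed in any pair. DESeq2 and limma-trend called 2 each, a fit with batch as a covariate 65 and a fit of the organoid libraries alone 521. The 2 libraries of each name are like neighbours, and summed they leave 1 each and no test. On simulated data for this comparison 45% of 4-fold changes and 0% of 2-fold changes were recovered.

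Correlation across genes placed the cultures among the embryonic stages. Spearman's rho over 11802 genes with the mean of each stage was highest with E7.5 for all 22 Day3 to Day6 libraries (Day6: 0.875 ± 0.0405 with E7.5 and 0.852 ± 0.0329 with E6.5, SD, n = 14). The 10 nEnd and organoid libraries were closest to E6.5 (nEnd: 0.778 ± 0.0235 with E6.5 and 0.745 ± 0.0221 with E7.5, n = 4). The lead of E7.5 over E6.5 was 0.01004 at Day3 and 0.0231 at Day6. Genes are not independent replicates, so no test was made. Without libraries of the other arm's signature only 1 of 20 Day3 to Day6 libraries remained closest to E7.5. Without either kind of doubted library, which leaves 2 E6.5 libraries, 19 of 30 culture libraries were closest to E7.5, 9 to E6.5 and 2 to E8.5.

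**Figure D4:**
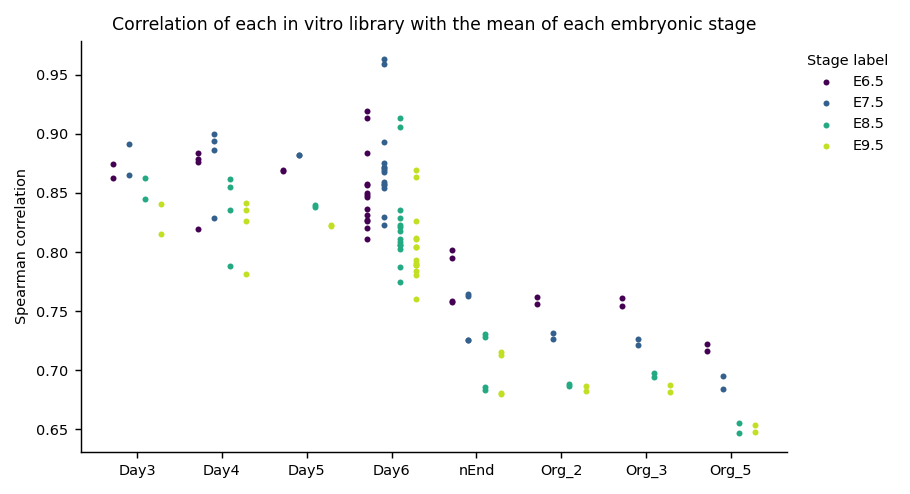
Spearman correlation across genes of each culture library (points) with the mean of the libraries of each stage label. With all libraries under their labels, Day3 to Day6 libraries are closest to E7.5, and nEnd and organoid libraries to E6.5. Without libraries of the other arm's signature 29 of 30 culture libraries are closest to E6.5, and without either kind of doubted library 9 of 30.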

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

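The arm signature, the plate-row tests, the tests of later clusters and Hox spread, the nEnd tests, the sums of like neighbours and the fit with library as a block below were chosen only after the result was seen. Of 173 sets of 4 to 10 libraries, 9 held 1 library far from the others by Dixon's test, and chance alone picks about 1 in 20. Fgf5, Tspan7 and Apoa2 were near 0 in nEnd, with Fgf5 at 0.981 CPM and Tspan7 at 1.96 CPM in library 2 and Apoa2 at 1.21 CPM in library 3, each at 0 in the other 3. In E7.5 visceral endoderm-like cells, Eomes stood at 32.1 CPM in library 2 (others 3.78 to 13.99), Utf1 at 29.3 in library 1 (others 0 to 12.8) and Ptpmt1 at 54.4 in library 1 (others 7.90 to 26.5). Among nEnd libraries, library 2 had 188 kept cells (others 189) and library 1 a median of 7458 UMIs per cell (others 4550 to 4874). Day4 library 4 had a correlation of 0.820 with E6.5 (others 0.877 to 0.884). Day6 library 14, of the next title and on the complementary well set, had 0.821.

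Visceral endoderm-like and definitive endoderm or gut-like cells changed differently from E7.5 to E8.5. An edgeR interaction test called 210 of 9930 genes, 105 in each direction. It treats the classes as separate samples, although libraries contribute to both. In the 12 libraries with both classes, 228 genes passed with each library as a block and 115 without it. Of the 228, 128 are among the 210, none in the opposite direction, and Gm1673, Amn, Slc7a9, Pllp and Apoa4 below did not pass. Hoxa7 (difference of log2 changes -6.35), Fabp1 (-6.23), Igfbp5 (-4.17), Cby1 (-3.77), Mycn (-3.295), Gm1673 (-3.29), Cdx2 (-2.90) and Apaf1 (-2.85) rose less, or fell more, in the visceral class. Fmr1nb (3.52), 0610005C13Rik (3.38), Apoa4 (3.37), Pllp (3.295), Soat2 (3.27), Ass1 (3.11), Slc7a9 (2.95) and Amn (2.95) did the opposite. Apoa4 and Amn are among the markers that name the visceral class, and Cdx2 among those of the gut-like class. Spike-in RNA, which no comparison uses, made up 0.0165% of UMIs in E6.5 library 4 and 3.06% in Day6 library 1.

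Cells with the other arm's signature filled 12 libraries to over 10%. Mixing of RNA between wells in comparable parts would put cells near the cutoff, and only 0.631% lay there, which argues against such mixing. Wells with little RNA of the other arm, or filled mostly by it, lie away from the cutoff, so the test cannot exclude these. If the culture signature belonged to definitive endoderm, cultures of the streak step should lack it. Day3 and Day4 libraries, which were not references, held 0% of cells with the embryo signature. This argues against definitive endoderm as its source in these cultures. Other cell types as the source were not tested and stay open. Definitive endoderm-like cells of the other E7.5 libraries carried the culture signature in 0.173% of cases, but those of the libraries full of it did so in only 0.621%, so the class leaves such cells out and the test is void. An exchange of labels between E7.5 and Day6 libraries predicted that all 4 libraries with over 90% of such cells would be closer to the other group across genes outside the signature, and 4 of 4 were (E7.5 library 5: rho 0.673 with E7.5 and 0.814 with Day6). The test does not say where an exchange took place.

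Hox genes stood high in 5 libraries labelled E6.5, from 151 to 304 CPM. Liver genes were at 2746 to 5115 CPM in 4 of them and 593 CPM in library 5, but also at 2510 and 2449 CPM in E6.5 libraries 3 and 4. A high level of the liver list is thus not particular to the 5. Alb of that list stood at 21.2 to 80.0 CPM in libraries 6, 7, 10 and 11. In the other E6.5 libraries, library 5 included, it stood at 0.655 CPM at most. Later clusters here are those in which E8.5 and E9.5 cells are over 50% once these 5 libraries and cells of the culture signature are set aside. Free RNA from later embryos in all wells was excluded as the whole source of Hox, since the variance of Hox UMIs between cells was at least 5.41 times that of a Poisson count in each. A part from free RNA stays open, as cells outside the later clusters still held 36.1 CPM of Hox. Sorting of several stages in blocks of plate rows predicted that the share of cells in later clusters differs between rows in all 5 libraries, and it did in 4 of 5 (permutation test). In libraries 6, 7, 10 and 11 it ran from 0% to 100% between rows, and library 5 did not pass (permutation p = 0.201). E6.5 libraries 1 and 2, outside the 5, also ran from 0% to 100%. Whole libraries of a later stage cannot be told apart from it over the 5 as a set, with 1 of 5 libraries, library 5, holding at least 90% of cells in later clusters. No biological explanation was tested.

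In nEnd libraries, naive pluripotency genes stood beside parietal endoderm genes. In libraries 1 and 2, Nanog stood 27.8 times higher in rows N to P than in the rest. Free RNA spread over the wells as its source is not excluded by this ratio, because Nanog itself served to choose the rows. Zfp42 and Esrrb, which did not, stood at 429 and 245 CPM in rows N to P against 20.6 and 12.7 in the rest. RNA spread evenly over the wells would not give this gap. These values argue against it as the main source of these naive genes, while a small part stays open. A separate kind of cell in these rows, which were chosen by Nanog, fits, with the parietal endoderm genes at 0.114 times their level in the other rows. The other rows still held 1111 CPM of Dppa5a, which this leaves open. In libraries 3 and 4, without Nanog, cells holding both gene sets fit, with rho across all cells of 0.46 and 0.548 between the lists. By rows it was 0.387 and 0.553 in rows A to M and 0.539 and -0.087 in rows N to P, so it is not found in each part of the plates, and free RNA was not tested there. Dppa5a made up most of the naive list there, at 1688 of 2197 CPM in library 3 and 2219 CPM in library 4. Zfp42 and Esrrb reached at most 20.3 CPM. The rho may thus rest mainly on Dppa5a and does not show a wider naive programme. In libraries 1 and 2 rho across all cells was -0.446 and -0.404. By rows it was 0.0152 and 0.0423 in rows A to M and 0.146 and 0.0028 in rows N to P. A biological reading, 1 cell state with both programmes, stays open for Dppa5a beside parietal endoderm genes.

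Splits of the same libraries into other groups were fitted 100 times for each count, the real split included, and in each case only 1 of the 100, the real one, reached the real count. The real count and the highest other were 1569 and 626 for E7.5 against E6.5, 3363 and 1292 for E8.5 against E7.5, and 91 and 90 for E9.5 against E8.5. They were 4185 and 1449 for nEnd against Day6, and 1626 and 428 for organoids against nEnd. In visceral endoderm-like cells they were 71 and 12 to E7.5 and 59 and 34 to E8.5, in definitive endoderm or gut-like cells 2264 and 5, and for the difference between classes 210 and 3. These splits part like neighbours. With like neighbours summed first, splits that reached the real count, the real one included, numbered 2 of 100 for E7.5 (498 genes, highest other 882), 1 of 100 for E8.5, 20 of 91 for E9.5 (3 genes), 1 of 66 for nEnd and 1 of 10 for organoids. They numbered 1 of 15 and 1 of 35 in the visceral class at E7.5 and E8.5 and 1 of 100 in the gut-like class. For E9.5 the count is thus no more than splits give, and 10 or 15 splits are too few to tell.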

How the results depend on the processing

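Tests within a batch, by signature, Hox level, plate rows, like neighbours or with library as a block were chosen only after the result was seen. Named genes kept direction and side of the threshold in 2887 of 3164 planned and 1059 of 1282 added checks, list calls in 704 of 758 and 266 of 294, and counts stayed within 1.5 times in 126 of 164 and 43 of 71. No paired analysis was possible between stages, days or cultures because titles number the libraries in 1 series and tie none to another. Plate layout is an exception, since it links libraries across day labels in sequencing batch 20. Day4 library 3 and Day6 library 13 fill complementary well sets under successive titles, as do Day4 library 4 and Day6 library 14. Their correlations with E6.5 were near equal (0.8837 and 0.8839, and 0.820 and 0.821). These links were not used in a test, and like neighbours were sought within a label only. Depth limits genes of few UMIs, most in Org_5 (at most 450717 UMIs per library). Where a value below moved, the cause was not tested, except that fewer libraries also test less.

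With sequencing batch as a covariate, counts were 320 (E7.5 against E6.5), 236 (E8.5 against E7.5), 0 (E9.5 against E8.5), 107 (Day4 against Day3) and 65 (among organoids). Log2 changes from E7.5 to E8.5 turned for Cxcr4 (0.30), Gsc (0.38), Hba-x (-1.20), Lefty1 (2.29) and Pga5 (0.35), from E6.5 to E7.5 for Cer1 (-0.90), and organoid changes for Aifm3 (2.40), Lamb3 (1.69) and Rpl10l (2.10). The epithelial junction call at Day6 turned (camera adjusted p = 0.527). With only the groups compared, counts were 776 (E7.5), 285 (E9.5), 0 (Day4) and 521 (among organoids). DESeq2 called 358 (E9.5), 95 (Day4), 2 (Day5), 14 (Day6), 2 (among organoids), and in visceral endoderm-like cells 132 (E7.5) and 102 (E8.5). Limma-trend called 2 at Day4 and 2 among organoids. At Day4, at least 500 UMIs gave 2 and leaving out ribosomal genes 2. Without a gene filter the visceral class gave 124 at E7.5 and 124 at E8.5, and at resolution 2 it gave 237 and 4, with Srgn at 0.14 (E8.5).

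Leaving out 1 library gave 6 to 228 genes for E9.5, 0 to 4 for Day4, 0 for Day5, Day6 and among organoids, 3323 to 3548 for nEnd, 985 to 1420 for organoids, 32 to 53 for the visceral class at E7.5 and 17 to 56 at E8.5, and 165 to 181 for the difference between classes. The E9.5 share difference ranged from -3.12 to -2.59 points. With nEnd libraries 1 and 2 alone, 2523 genes passed against Day6. With libraries 3 and 4 alone, 898 passed in organoids, with Aifm3 at 2.40 and Lamb3 at 1.70.

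Without libraries of the other arm's signature, counts were 947 (E7.5), 2107 (E8.5), 239 (E9.5), 3 (Day4), and 16 (E7.5) and 38 (E8.5) in the visceral class. Cxcr4 at E8.5 was 0.13, Klf2 at E7.5 0.29, and 1 of 30 culture libraries was closest to E7.5, against 19 of 30 without either kind of doubted library. With own-arm cells only, counts were 311 (E9.5) and 3 (Day4), Gsc at E7.5 was -2.51 (a fall that passed, adjusted p = 0.00287), Klf2 0.15 and Cxcr4 at E8.5 0.42. Without libraries of over 25% variance between plate rows, counts were 405 (E7.5), 2221 (E8.5), 287 (E9.5) and 0 (Day4), with Ambp at 0.27, Dlk1 at 0.086 and Klf2 at 0.54 (E7.5). Without the Hox-high E6.5 libraries, Ambp was 0.46, Dlk1 0.68 and Serpina1b 1.38. Without either kind of doubted library, Ambp was 0.15, Arg1 2.90, Dlk1 0.26, Itih2 0.58, Klf2 1.003, Serpina1b 0.69 and the Hox list had adjusted p = 0.822 by camera in the other direction.

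Within batch 13, Gsc at E7.5 was -3.84 (passed, edgeR adjusted p = 1.29e-06). Within batch 3, 686 genes passed at E8.5, with Cdh1 at 0.0076, Cer1 0.52, Cxcr4 0.53, Gsc 0.0066, Hhex 1.002 (passed, edgeR adjusted p = 0.0213), Lefty1 1.80, Otx2 0.053, Pga5 1.80, Dnmt3b 0.51 and Fgf5 0.95. There the floor plate, epiblast and anterior visceral endoderm lists turned (camera adjusted p = 0.761, 0.253 and 3.51e-06). Within batch 7, 271 passed at E9.5. Within batch 15, 989 passed at Day5, with Hhex at 2.72 (passed, edgeR adjusted p = 4.31e-10), and 403 at Day6. Within batch 21, 3189 passed in organoids. With anterior visceral endoderm-like clusters counted, the E7.5 share difference was -22.4 points.

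With like neighbouring libraries summed, counts were 498 (E7.5), 2140 (E8.5), 3 (E9.5), 0 (Day4), 2082 (nEnd), 131 (organoids), and 23 (E7.5) and 24 (E8.5) in the visceral class. The fall of the visceral share at E8.5 lost its call (-6.14 points, exact adjusted p = 0.0955).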

Other observations

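The comparison between classes below was chosen only after the result was seen. From E7.5 to E8.5, genes of lipid carriage fell less, or rose more, in visceral endoderm-like cells than in definitive endoderm or gut-like cells (7 of 15 called so and 1 the other way; camera adjusted p = 7.45e-16; 0.0138 with an estimated correlation, lost at 0.108 with library as a block). The list of uptake and lysosome genes did so in 7 of 19 cases with 1 the other way (0.000115), a call lost with an estimated correlation (0.12). Apoa1, Apoa4, Apob, Apoc2, Apoe, Apom, Ttr and Rbp4 of the first list and Amn, Cubn and Dab2 of the second name the visceral class. Both differences thus follow in part from the naming. Glycolysis genes went the other way in 4 of 17 cases (camera adjusted p = 7.33e-05, and 0.0355 with an estimated correlation). With library as a block 10 of 15 did (7.28e-10 and 0.00514). Amn, the membrane anchor of the cubilin receptor, differed between the classes by 2.95 on the log2 scale and Apoa4, an apolipoprotein, by 3.37, and both missed the threshold with library as a block (edgeR adjusted p = 0.052 and 0.0912). Amn and Apoa4 are naming markers, and their fall in the gut-like class cannot be told apart from the loss of cluster 11. The posterior gene Cdx2 differed by -2.90 and Hoxa7 by -6.35, rising in the gut-like class, where Cdx2 is among the naming markers. The edgeR interaction test called 210 genes, 143 without libraries of the other arm's signature, 228 with library as a block in the 12 libraries with both classes and 65 with like neighbouring libraries summed.

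Plate rows carried information on the cells in 44 of 75 libraries. In nEnd libraries 1 and 2, rows N to P held 71 kept cells and rows A to M 306, with Sparc at 582 CPM against 5546 CPM in rows A to M and Zfp42 at 429 against 20.6 CPM. Clusters in which E8.5 and E9.5 cells are over 50%, with the Hox-high E6.5 libraries and cells of the culture signature set aside, held a median of 0% of the cells of E7.5 libraries and 49.5% of E6.5 libraries. For E8.5 libraries, on which the clusters were chosen, it ran from 39.5% to 99.5%.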
